A study of Homo sapiens with 8 samples.

How the data were processed

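RNA of LN229, an established human glioblastoma cell line, was measured on expression arrays in 8 samples that fall into 2 groups of 4. One condition was compressive solid stress (CSS) of 23 Pa for 18 h and the other was culture without it. Cells grew on the polyester membrane of a Transwell insert, and the pressure came from stainless-steel discs lying on an agar cushion. Control wells had neither cushion nor discs, so that every difference between the conditions compares both together with neither.

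The labels of each sample contradict one another. Every title that names a control belongs to a sample whose source name and description state 23 Pa CSS, and every title that names 23 Pa CSS belongs to a sample described as uncompressed. Groups were taken from the titles, and each signed difference is the mean of the samples titled 23 Pa CSS minus the mean of the samples titled no CSS. If the source names and descriptions are right, every sign turns and the counts of higher and lower transcripts change places. The values were not used to settle this.

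The deposited table holds a log2 signal for each transcript cluster and sample, which per the labels the authors made with Transcriptome Analysis Console (no version stated). The summarisation, the normalization and the genome build are not stated, and the column medians of the deposited values differ slightly. The series text names the Human Transcriptome Array 2.0, and the identifiers of 2197 positive and 612 negative control rows begin with HTA2. The identifiers of the transcript clusters, however, are of a form used by another array of the same maker, so no position in the genome is given here. Array signal carries no count, and its precision is limited by the number of arrays. The table has 138745 rows. Of these, 2995 control rows were set aside and 135750 transcript clusters were tested, without a filter on low signal. Exactly 1 gene symbol was given for 36176 of them, several for 1119 and none for 98455. Symbols were matched to a human gene table by Entrez identifier for 25516 transcript clusters, by symbol for 9899 and by synonym for 623, and 138 found no match. This gave 33458 genes, of which 1707 had several transcript clusters, and the one with the highest mean over the 8 samples stood for the gene.

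Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with the default prior, two-sided, 6 residual and 5.28 prior degrees of freedom). Tables were read with the R package data.table, version 1.17.8, and figures were drawn with matplotlib 3.10.9 in Python 3.11.15. P-values were adjusted with the Benjamini-Hochberg method over all 135750 transcript clusters, and those with an adjusted p under 0.05 were taken as changed. Nothing in the labels says whether the 4 samples of a group are separate cultures, so the p-values measure only the spread between these samples. Before the data were examined, 50 gene lists were fixed. They cover responses to hypoxia, mechanical force and stress, metabolism, the cell cycle, the states of glioblastoma, families of small RNAs and other genes, and markers of cell types other than the cell line. Of these, 49 had at least 3 measured genes and were tested with limma's camera at a preset correlation between genes of 0.01, adjusted over the lists. Camera with an estimated correlation, fry and an exact test were run beside it. The exact test compared the median difference of a list with its values over all 35 splits of the 8 samples into 4 and 4, where the smallest p is 0.0286. Single values were compared with a two-sided exact permutation test over all 70 assignments of the samples. Intervals of 95% for list medians came from 2000 bootstrap samples of the members, and random lists matched for signal were drawn 10000 times. Both leave out the correlation between genes of a list, and neither measures the spread between samples.

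The rule for named genes was fixed before the data were examined as well. It took genes past the threshold whose groups did not overlap, and of these the 10 with the largest rise and the 10 with the largest fall. It added up to 4 members with the smallest p of each gene list and 12 genes chosen for the question. Any other gene is said to have been chosen after its values were seen.

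The procedure was tested on simulated data in which each transcript cluster had 1 spread, pooled over the 2 groups of these samples. Real spreads could differ between the groups, as for CENPF (SD 0.0712 titled no CSS and 1.47 titled 23 Pa CSS). The simulation does not cover such genes. Of 50 transcript clusters given a log2 change of 1, 36% were recovered, and the shares were 82%, 96% and 100% at log2 changes of 2, 3 and 4. Among 135750 transcript clusters without a change 0 were called, and 7 unchanged ones were called beside 200 changed ones. Of 49 simulated lists 0 passed when none was shifted, and 1 passed when 1 was shifted. The noise was drawn for each transcript cluster on its own, so simulated genes did not move together. In the real data the estimated correlation was 0.135 in the hypoxia list and 0.641 in the glycolysis list. The simulation therefore does not show how often camera calls such lists by error.

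Alternatives fixed in advance were a block for the replicate number, quantile normalization, median centring, a filter at the median signal, restriction to transcript clusters with a symbol, a trended and robust prior, array weights, an unmoderated test, other thresholds, the mean of all transcript clusters of a gene, groups from the source names, and leaving out each sample in turn. Centring each array on its hybridisation controls was added after the data had been seen. CA9, one of the genes chosen for the question, was not analysed here.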

Results

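The data comprised log2 signal from 8 arrays of LN229 glioblastoma cells, 4 from samples titled no CSS and 4 from samples titled 23 Pa CSS. Signal spanned 2.10 to 19.93 on the log2 scale, and the column medians lay between 4.56 and 4.65. Antigenomic background probes averaged 4.03 in the samples titled no CSS and 4.18 in those titled 23 Pa CSS. The only comparison asked which transcripts differ between cells held under 23 Pa for 18 h and cells held under none. Every difference is titled 23 Pa CSS minus titled no CSS on the log2 scale, with n = 4 per group, and its sign turns if the source names rather than the titles are right. Genes rose or fell where limma gave an adjusted p under 0.05.

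In the samples titled 23 Pa CSS, STC1 (transcript cluster TC0800009891.hg.1), which encodes a secreted glycoprotein, rose 13.7-fold, from 11.36 ± 0.449 to 15.14 ± 0.121 (SD, n = 4, limma adjusted p = 0.000211). TMEM45A, a transmembrane protein, rose 10.4-fold, from 8.49 ± 0.258 to 11.87 ± 0.313 (SD, adjusted p = 0.000211). CENPE, the kinetochore motor that helps chromosomes to align, fell from 13.06 ± 0.312 to 9.70 ± 0.868, a difference of −3.36 (SD, adjusted p = 0.00463). CENPF, another kinetochore protein, fell from 15.59 ± 0.0712 to 12.40 ± 1.47, a difference of −3.19 (SD, adjusted p = 0.0204). The SD of the samples titled 23 Pa CSS was thus 1.47 for CENPF and 0.121 for STC1. For CENPF the SD also differed between the groups, as it did for KIF14 (0.101 titled no CSS and 1.34 titled 23 Pa CSS). The limma fit and the unmoderated test both assume an equal spread in the 2 groups. No test without this assumption was run, so the p-values of such genes rest on it.

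Among the 10 genes with the largest rise, several belong to the hypoxia response or to energy metabolism. NDRG1, a stress-responsive gene, rose by 2.65 (adjusted p = 0.00114), and ADM, which encodes the vasodilator peptide adrenomedullin, rose by 2.64 (adjusted p = 0.00114). ALDOC, a glycolytic aldolase, rose by 2.54 and AK4, a mitochondrial adenylate kinase, by 2.51 (adjusted p = 0.00129 for both). SLC2A1, the glucose transporter of many tumour cells, rose by 2.22 (adjusted p = 0.00247). THBS1, the matrix glycoprotein thrombospondin, rose by 2.40 (adjusted p = 0.00432), and SLAMF9, a receptor of the immunoglobulin superfamily, rose by 2.70 (adjusted p = 0.0075). Of the 10 genes with the largest fall, 7 act in mitosis: beside CENPE and CENPF these were the spindle-pole protein ASPM (−2.86), the kinesins KIF18A (−2.83), KIF20B (−2.82) and KIF14 (−2.78), and SGO2, which protects sister-chromatid cohesion (−2.57). HMGN5, which binds nucleosomes, differed by −2.78. The adjusted p of these 6 genes after CENPF lay between 0.00685 for SGO2 and 0.0245 for KIF14. Pseudogenes of BNIP3 went both ways: BNIP3P1 rose by 2.62, whereas BNIP3P7 (−2.57, adjusted p = 0.0289) and BNIP3P3 (−2.51, adjusted p = 0.0272) fell, and sequence shared with BNIP3 was not examined here.

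**Figure D1:**
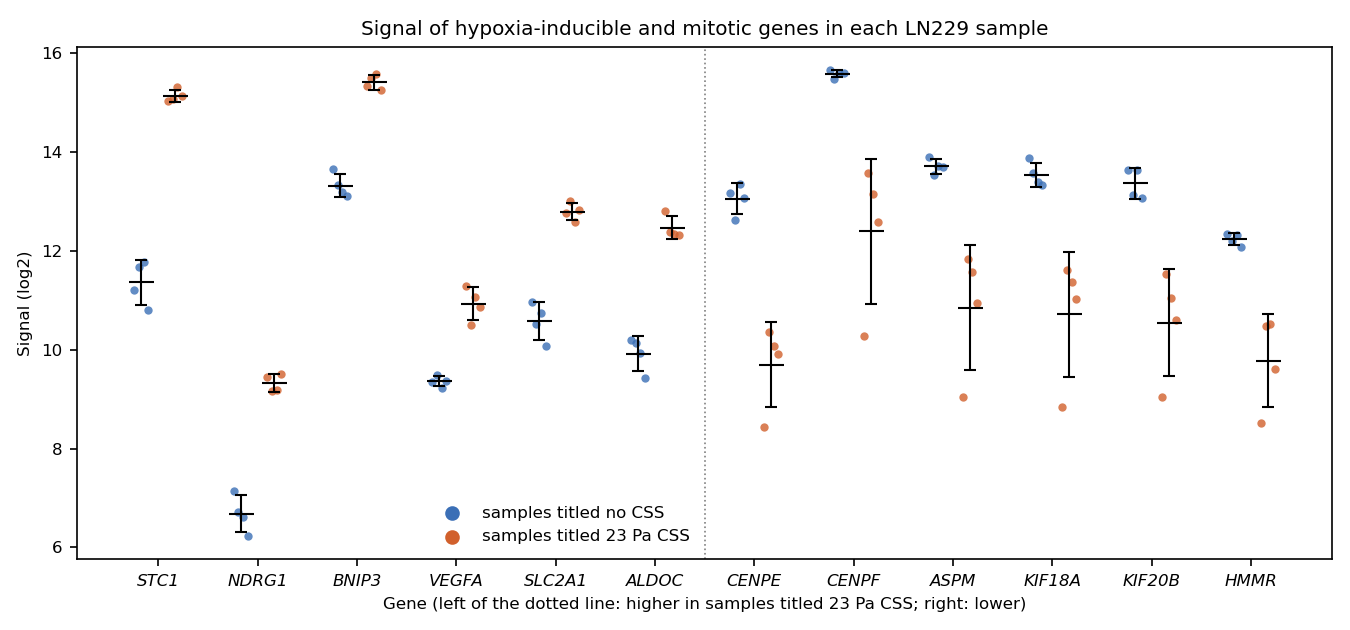
Signal (log2) of 6 genes higher and 6 genes lower in the samples titled 23 Pa CSS, with 1 point per sample and bars for mean ± SD (n = 4 per group). For CENPF the samples titled no CSS lie within an SD of 0.0712 and those titled 23 Pa CSS within an SD of 1.47.

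Across all transcript clusters, 2727 changed at an adjusted p under 0.05, 789 higher and 1938 lower. Of these, 478 were at least 2-fold higher and 1693 at least 2-fold lower, and 21784 had an unadjusted p under 0.05. Of the changed transcript clusters with exactly 1 symbol 57.1% were higher, against 16% of those with no symbol, a difference that was not tested. Counted by gene, 777 changed, 455 higher and 322 lower, and the groups did not overlap in any of the 777. So strict a threshold favours genes without overlap, so this is no separate support for them. Groups did not overlap in 13.7% of all 33458 genes, where chance gives 2.86%. The balance depended on scaling: quantile normalization gave 1126 higher and 1448 lower transcript clusters, and centring on hybridisation controls 373 higher and 8208 lower.

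The count rested on single samples: it was 1295, 438, 1087 and 411 without titled no CSS replicates 1, 2, 3 and 4, and 901, 1285, 5360 and 580 without titled 23 Pa CSS replicates 1, 2, 3 and 4. Of 118 changed genes followed singly, not all of them named in the text, 81 lost their call without at least 1 of the samples. The 11 that kept theirs under each of 18 alternatives included STC1, TMEM45A, NDRG1, ADM, ALDOC, AK4, BNIP3, PFKP and BHLHE40, whereas CENPF, ASPM, KIF18A and KIF14 lost theirs without any 1 of the samples titled no CSS and without titled 23 Pa CSS replicate 4, with adjusted p of at most 0.195.

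Many of the measured genes induced by low oxygen rose. Of 24 members of the hypoxia list, 15 rose, 0 fell and 9 did not pass, and 18 were higher adjusted over the list alone. On arrays centred on hybridisation controls, and with a block for the replicate number, 11 rose. BNIP3, a mitophagy receptor, rose from 13.32 ± 0.237 to 15.41 ± 0.149 (SD, n = 4, limma adjusted p = 0.00136), as did NDRG1, ADM and SLC2A1. VEGFA, the main angiogenic growth factor, rose from 9.36 ± 0.104 to 10.93 ± 0.338 (SD, adjusted p = 0.00714). The median difference of the list was 1.07 (camera adjusted p = 1.31e-19, and adjusted p = 0.1 with an estimated correlation), and its median in the single samples titled 23 Pa CSS was 0.916, 0.987, 1.5 and 1.03. Of 16 glycolytic enzymes, 10 rose, 0 fell and 6 did not pass, and 13 were higher adjusted over the list alone. Beside ALDOC these included PGK1 (2.08, adjusted p = 0.00449), the hexokinase HK2 (2.07, adjusted p = 0.0059) and the phosphofructokinase PFKP (1.33, adjusted p = 0.00694). The median difference of the list was 1.15 (camera adjusted p = 3.57e-14, and adjusted p = 0.277 with an estimated correlation). LDHA and GAPDH, named after their values were seen, lay at 19.91 and 19.88 in the samples titled 23 Pa CSS, close to the table's maximum of 19.93, where a rise cannot be seen. Their differences were 0.28 and 0.16 (adjusted p = 0.416 and 0.685).

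**Figure D2:**
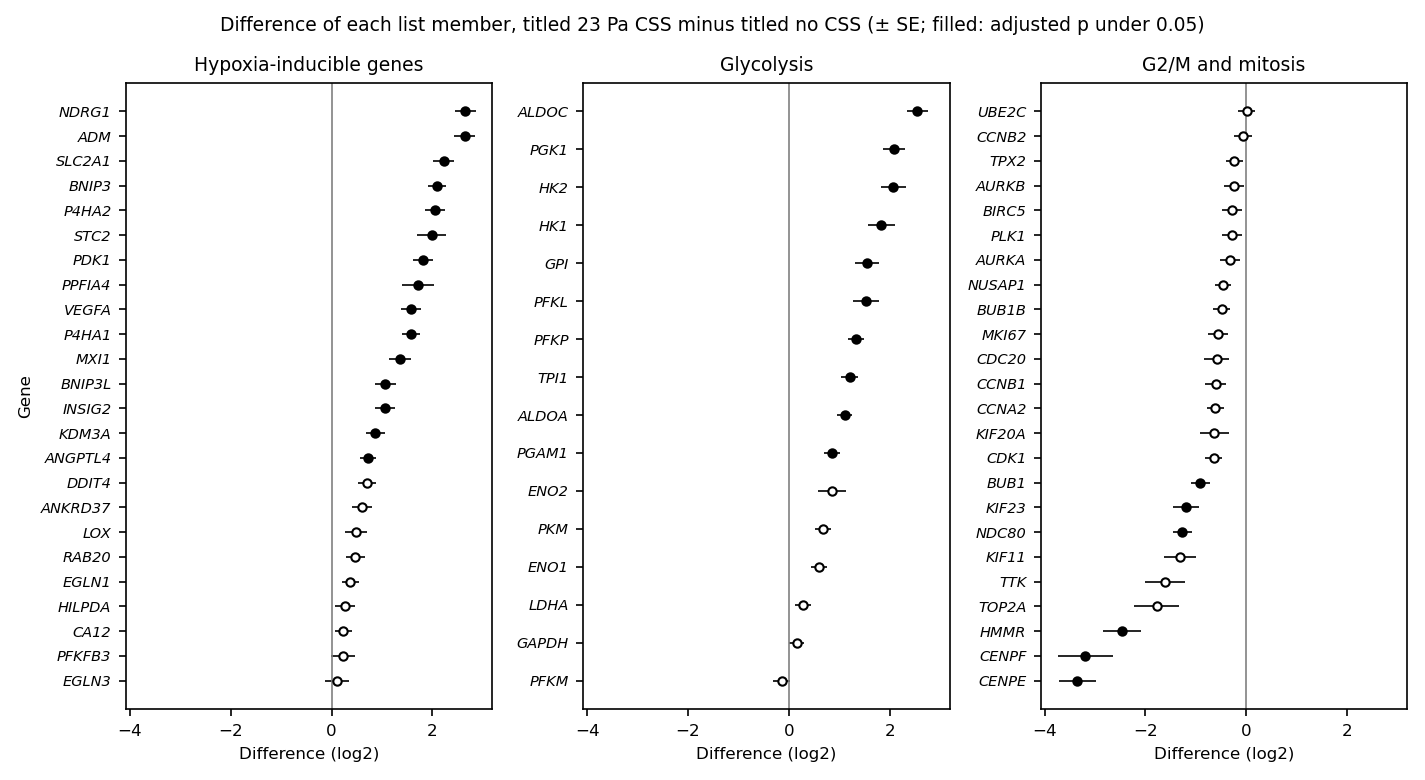
Log2 difference of each measured member of 3 gene lists, titled 23 Pa CSS minus titled no CSS, with the standard error of the limma estimate and filled points where the adjusted p was under 0.05. In the hypoxia list 15 of 24 members rose, in the glycolysis list 10 of 16, and in the G2/M list 6 of 24 fell.

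Cell cycle genes changed in part. Of 24 measured G2/M genes, 6 fell, 0 rose and 18 did not pass, and 15 were lower adjusted over the list alone. On arrays centred on hybridisation controls 17 fell, and with a block for the replicate number 4. The 6 were CENPE, CENPF, the kinetochore component NDC80 (−1.27, adjusted p = 0.0129), the spindle protein HMMR (−2.46, adjusted p = 0.0139) and, named after their values were seen, the checkpoint kinase BUB1 (−0.92, adjusted p = 0.035) and the cytokinesis motor KIF23 (−1.19, adjusted p = 0.0435). The list's median difference was −0.609 (camera adjusted p = 2.5e-17, and adjusted p = 0.186 with an estimated correlation). MKI67, the proliferation marker, was 15.07 ± 0.125 and 14.51 ± 0.35 (SD, n = 4, limma adjusted p = 0.181). In the G1/S list, 1 of 24 genes rose, the replication licensing factor CDT1 (1.09, adjusted p = 0.0215), 23 did not pass, and 11 were higher adjusted over the list alone. Its median difference was 0.444 (camera adjusted p = 0.000483, and adjusted p = 0.503 with an estimated correlation). SLBP, GINS2 and UHRF1 differed by 0.89, 0.73 and 0.68 (adjusted p = 0.0637, 0.0695 and 0.0808). CDT1 lost its call on arrays centred on hybridisation controls, with a block for the replicate number and without any 1 of 5 single samples. Of 30 histone genes 0 passed limma's threshold, 5 had an unadjusted p under 0.05 and 0 passed adjusted over the list alone, with a median of 0.213 (camera adjusted p = 0.0567).

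Some target genes of mechanical signalling rose. Of 22 YAP/TAZ targets, 4 rose and 18 did not pass, while 10 were higher and 1 lower adjusted over the list alone. CCN1 rose from 5.54 ± 0.252 to 6.76 ± 0.455 (SD, n = 4, limma adjusted p = 0.0294) and CCN2 from 7.07 ± 0.325 to 8.13 ± 0.277 (adjusted p = 0.0314). Both encode matricellular proteins. CRIM1 (1.01) and the phosphatase PTPN14 (0.82) rose as well, whereas ANKRD1 (3.54 and 4.13) lay below the antigenomic background in both groups. The median of this list was 0.479 (camera adjusted p = 0.000255, and adjusted p = 0.287 with an estimated correlation). Of 17 SRF/MRTF targets of the actin cytoskeleton, 3 rose: the actin cross-linker FLNA (1.44), the focal-adhesion protein TGFB1I1 (1.36) and the calponin CNN2 (1.21). The other 14 did not pass, 9 were higher and 1 lower adjusted over the list alone, and the median was 0.425 (camera adjusted p = 0.000587, and adjusted p = 0.192 with an estimated correlation). CCN1, CCN2, CRIM1 and PTPN14 each lost their call on arrays centred on hybridisation controls, CCN2, PTPN14 and CNN2 with a block for the replicate number, and all 5 without several single samples.

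Immediate early genes had a median of 0.19 (camera adjusted p = 0.00442, and adjusted p = 0.544 with an estimated correlation), which became −0.121 on arrays centred on hybridisation controls. Of 19 members 3 rose, the transcription factors JUN (1.62, limma adjusted p = 0.0141), MYC (0.93, adjusted p = 0.0477) and EGR3 (0.84, adjusted p = 0.0469), 16 did not pass, and 5 were higher adjusted over the list alone. FOS differed by 0.22 (adjusted p = 0.747). MYC and EGR3 lost their calls on arrays so centred and with a block for the replicate number. MYC also lost its call without any 1 of the 8 samples, and EGR3 without any 1 except titled 23 Pa CSS replicate 3. The list median was 0.3 with quantile normalization, 0.317 without titled no CSS replicate 3 and 0.305 without titled 23 Pa CSS replicate 2. Of 15 feedback genes of the ERK pathway 0 passed limma's threshold, 8 had an unadjusted p under 0.05, and 5 were higher adjusted over the list alone. SPRY1, ETV5, SPRED2 and DUSP4 differed by 0.99, 0.82, 0.68 and 0.66, and the median was 0.352 (camera adjusted p = 0.0287, and adjusted p = 0.544 with an estimated correlation). The camera call of this list was lost without titled no CSS replicate 4 and among genes above the median signal.

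Of the genes that sense force or hold cells to the matrix, most did not pass. Among 14 mechanosensitive channels and their relatives 0 passed limma's threshold, 5 had an unadjusted p under 0.05, and 2 were higher and 1 lower adjusted over the list alone, with a median of 0.224 (camera adjusted p = 0.324). PIEZO1, a stretch-gated channel, was 6.16 ± 0.43 and 6.31 ± 0.125 (SD, n = 4, limma adjusted p = 0.795). Of 23 integrins and focal-adhesion genes 1 rose, the laminin receptor subunit ITGA3 (1.28), and 22 did not pass; adjusted over the list alone 8 were higher and 3 lower, and the median was 0.214 (camera adjusted p = 0.144). Of 23 motility genes 3 rose, the small GTPase RHOB (1.17), the actin bundler FSCN1 (0.96) and the myosin MYH9 (1.01), and 1 fell, the formin DIAPH3 (−1.07). The other 19 did not pass, 9 were higher and 3 lower adjusted over the list alone, and the median was 0.379 (camera adjusted p = 0.15). With the mean of its transcript clusters MYH9 differed by 0.249 and lost its call, and DIAPH3 lost its call under quantile normalization.

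Matrix genes went both ways. Of 23 matrix components THBS1 and the collagen chain COL5A1 (1.06) rose, the proteoglycan VCAN (−1.43) and the laminin chain LAMA4 (−1.07) fell, and 19 did not pass. Adjusted over the list alone 4 were higher and 2 lower, and the median was 0.235 (camera adjusted p = 0.144). On arrays centred on hybridisation controls it was −0.0762, and the list passed camera's threshold (adjusted p = 0.0481). Of 22 matrix proteases and inhibitors 1 rose, the membrane protease MMP14 (0.91), 21 did not pass, and 2 were higher and 2 lower adjusted over the list alone (median 0.149, camera adjusted p = 0.662). MMP2, a gelatinase, was 17.14 ± 0.0812 and 17.47 ± 0.0994 (SD, n = 4, limma adjusted p = 0.322). Of 17 TGF-beta targets 2 rose, the transcription repressor BHLHE40 (2.09, adjusted p = 0.00206) and CCN2, and 15 did not pass. Adjusted over the list alone 11 were higher and 1 lower, and the median was 0.591 (camera adjusted p = 0.000891, and adjusted p = 0.277 with an estimated correlation). ID2 and LTBP3 differed by 0.65 and 0.80 (adjusted p = 0.0574 and 0.08). The cytokine TGFB1 itself rose (1.46, adjusted p = 0.0219), the only one of 15 mesenchymal-transition genes to pass. In that list 5 were higher and 3 lower adjusted over the list alone, with a median of 0.271 (camera adjusted p = 0.324).

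Few markers of glioblastoma states changed. Of 16 markers of the mesenchymal state the calcium-binding proteins S100A10 (1.17, limma adjusted p = 0.011) and S100A11 (1.02, adjusted p = 0.018) rose, 14 did not pass, and 6 were higher adjusted over the list alone. CD44 and LGALS1 differed by 0.53 and 0.51 (adjusted p = 0.094 and 0.124). The median was 0.434 (camera adjusted p = 0.00229, and adjusted p = 0.342 with an estimated correlation). Of 14 proneural and progenitor markers PTPRZ1, a receptor phosphatase of glial progenitors, fell (−1.38, adjusted p = 0.0206) and 13 did not pass, and 1 was higher and 2 lower adjusted over the list alone. That list's median was 0.133 and its mean −0.0221, and camera gave a downward direction (adjusted p = 0.764).

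Stress pathways changed in single genes. Of 20 ATF4 and amino-acid response genes, the subunits of an amino-acid transporter SLC7A5 (1.27) and SLC3A2 (0.98) and the lipoprotein receptor VLDLR (1.40) rose, and 17 did not pass, with 6 higher and 1 lower adjusted over the list alone. DDIT4 differed by 0.71 (adjusted p = 0.0659), and the list's median of 0.279 (camera adjusted p = 0.0295, and adjusted p = 0.544 with an estimated correlation) became −0.0319 on arrays centred on hybridisation controls. Of 14 NRF2 targets the malic enzyme ME1 (1.65), the ferritin light chain FTL (1.05) and the aldo-keto reductase AKR1C1 (1.46) rose, and 11 did not pass, with 5 higher and 1 lower adjusted over the list alone. Their median of 0.226 (camera adjusted p = 0.0143, and adjusted p = 0.342 with an estimated correlation) became −0.0854 on arrays so centred. HMOX1, the inducible heme oxygenase, differed by 0.56 (adjusted p = 0.275). AKR1C1 lost its call without any 1 of the 8 samples, whereas ME1 kept its call whichever sample was left out. FTL lost its call without titled no CSS replicate 2 or 4 and without titled 23 Pa CSS replicate 1 or 4. Of 17 autophagy and lysosome genes the protease CTSD (1.37) and GABARAPL1 (1.67), which acts on autophagosomes, rose, 15 did not pass, and 5 were higher adjusted over the list alone. Their median of 0.308 (camera adjusted p = 0.027, and adjusted p = 0.544 with an estimated correlation) became −0.00311 on arrays so centred. The camera calls of the ATF4 and autophagy lists were lost without titled no CSS replicate 4 and without titled 23 Pa CSS replicate 1. That of the ATF4 list was also lost with a block for the replicate number (adjusted p = 0.0505) and among genes above the median signal (adjusted p = 0.0555), and fry did not call the autophagy list, whose median was 0.189 with the mean of all transcript clusters of a gene.

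Of 19 p53 targets the nuclease gene AEN rose (1.08, limma adjusted p = 0.0402), 18 did not pass, and 5 were higher and 1 lower adjusted over the list alone (median 0.253, camera adjusted p = 0.324). CDKN1A, the cell cycle inhibitor p21, was 10.60 ± 0.268 and 11.20 ± 0.231 (SD, n = 4, adjusted p = 0.148). Among 13 heat shock chaperones the co-chaperone BAG3 rose (1.01), CHORDC1, which binds HSP90, fell (−1.44), and 11 did not pass, with 2 higher and 2 lower adjusted over the list alone (median −0.0222, camera adjusted p = 0.48). Of 16 genes of the unfolded protein response EDEM1, a factor of protein degradation, rose (1.13) and 15 did not pass, with 2 higher and 1 lower adjusted over the list alone (median 0.113, camera adjusted p = 0.967). In 10 metallothioneins 0 passed limma's threshold, 2 had an unadjusted p under 0.05 and 0 passed adjusted over the list alone (median 0.311, camera adjusted p = 0.217). Among 17 apoptosis regulators 0 passed, 5 had an unadjusted p under 0.05 and 1 was higher adjusted over the list alone (median 0.278, camera adjusted p = 0.662). EDEM1 lost its call with the mean of its transcript clusters.

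Of 15 cholesterol synthesis and uptake genes 0 passed limma's threshold, 4 had an unadjusted p under 0.05, and 3 were lower adjusted over the list alone. INSIG1, IDI1, STARD4 and FDPS differed by −1.02, −0.79, −1.08 and −0.61 (adjusted p = 0.0606, 0.0735, 0.0863 and 0.189). The median of the list was −0.192 (camera adjusted p = 0.00426, and adjusted p = 0.544 with an estimated correlation), and fry did not call it (adjusted p = 0.263). It was −0.0728 without titled no CSS replicate 2, −0.0565 without titled 23 Pa CSS replicate 2 and −0.461 without titled 23 Pa CSS replicate 1. Of 57 cytosolic ribosomal protein genes, 0 passed limma's threshold, 29 had an unadjusted p under 0.05 and 2 were higher adjusted over the list alone. RPS12, RPLP1, RPS19 and RPS15A differed by 0.70, 0.74, 0.57 and 0.50 (adjusted p = 0.0514, 0.0585, 0.118 and 0.119), and the median was 0.365 (camera adjusted p = 9.47e-07, and adjusted p = 0.544 with an estimated correlation). The spiked hybridisation controls, which carry no cellular RNA, differed by 0.311 in the same direction. Of 20 respiratory chain subunits 0 passed, 6 had an unadjusted p under 0.05 and 1 was higher adjusted over the list alone (median 0.277, camera adjusted p = 0.144). Of 11 housekeeping genes PGK1 rose and 10 did not pass, with 3 higher and 1 lower adjusted over the list alone (median 0.313, camera adjusted p = 0.0589).

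Other signalling lists gave few calls. Of 13 Wnt targets the cyclin CCND1 (0.96, limma adjusted p = 0.0244), the Wnt inhibitor DKK1 (1.15, adjusted p = 0.0363) and MYC rose, 10 did not pass, and 3 were higher adjusted over the list alone (median 0.155, camera adjusted p = 0.15). Among 12 water, osmotic and volume regulators the taurine transporter SLC6A6 rose (1.30), and 11 did not pass, with 3 higher and 1 lower adjusted over the list alone (median 0.119, camera adjusted p = 0.574). In 21 NF-kappaB targets and cytokines 0 passed limma's threshold, 4 had an unadjusted p under 0.05 and 0 passed adjusted over the list alone. Their median was 0.154 and their mean −0.00798, and camera gave a downward direction (adjusted p = 0.8). For 21 interferon-stimulated genes these counts were 0 and 4, with 1 higher and 1 lower adjusted over the list alone, and camera gave a downward direction beside a median of 0.0382 (adjusted p = 0.818). For 13 Notch genes they were 0 and 2, with 0 adjusted over the list alone (median 0.21, camera adjusted p = 0.662). For 12 gap junction and cadherin genes they were 0 and 0, with 0 adjusted over the list alone (median 0.189, camera adjusted p = 0.761). GJA1, which encodes connexin 43, was 9.45 ± 0.494 and 9.19 ± 0.085 (SD, n = 4, adjusted p = 0.653). DKK1 lost its call with the mean of its transcript clusters, and MYC without any 1 of the 8 samples.

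Small RNA genes of the miR-548 family, a large group of primate microRNAs, fell in part. Of 72 measured genes with this symbol, 1 of them a host gene rather than a microRNA, 5 fell, 0 rose and 67 did not pass, and 10 were lower adjusted over the list alone. They were MIR548T (−1.16, limma adjusted p = 0.0154), MIR548H2 (−0.88, adjusted p = 0.0311), MIR548AZ (−0.98, adjusted p = 0.0401), MIR548AJ2 (−0.95, adjusted p = 0.049) and, named after its value was seen, MIR548AA1 (−0.79, adjusted p = 0.0495). The median was −0.422 (camera adjusted p = 5.29e-13, and adjusted p = 0.192 with an estimated correlation), and −0.401 for the 71 microRNAs alone. Over all 1498 genes with a microRNA symbol, 28 of them annotated as another biotype, 18 fell, 2 rose and 1478 did not pass, with 11 lower adjusted over the list alone. Of the 1470 annotated as microRNAs 17 fell and 2 rose. MIR924 (−1.74), MIR604 (−1.66), MIR454 (−1.21) and MIR7978 fell, and MIR3654 (0.81) and MIR3611, named after their values were seen, rose. MIR7978 went from 4.84 to 3.44 and MIR3611 from 3.47 to 5.23, so that each was below the antigenomic background in 1 group and the size of its change is not known. The median of all genes with a microRNA symbol was −0.0307 (camera adjusted p = 0.000255, and adjusted p = 0.192 with an estimated correlation), and fry did not call them (adjusted p = 0.189). It was −0.0296 for the 1470 microRNAs and −0.00493 for all without titled no CSS replicate 4. The signal of these transcript clusters does not tell a mature microRNA from its precursor. MIR548H2, MIR548AJ2 and MIR548AA1 lost their calls under quantile normalization.

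Of 153 C/D box small nucleolar RNAs, many of which guide methylation of ribosomal RNA, 12 rose, 2 fell and 139 did not pass, with 25 higher and 3 lower adjusted over the list alone. SNORD116-2 (1.31), SNORD24 (1.23) and SNORD8 (1.01) rose, and SNORD55 (−1.57) and, named after its value was seen, SNORD56 (−1.67) fell. With a block for the replicate number 1 rose and 2 fell. The median was 0.164 (camera adjusted p = 0.0961), and −0.147 on arrays centred on hybridisation controls, where the list passed camera's threshold (adjusted p = 0.0155). Of 95 H/ACA box small nucleolar RNAs, which guide pseudouridylation, SNORA20, SNORA24 (1.03), SNORA13 (0.84) and SNORA71C (0.75) rose and 91 did not pass, with 12 higher and 3 lower adjusted over the list alone. Their median of 0.167 (camera adjusted p = 0.292) became −0.144 on arrays so centred. SNORA20 went from 3.76, below the antigenomic background, to 4.84, so the size of its rise is not known. SNORD55, SNORD56, SNORA20 and SNORA24 lost their calls with the mean of their transcript clusters, and SNORD116-2, SNORD24, SNORD8, SNORA24, SNORA13 and SNORA71C with the block.

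Of 454 zinc finger protein genes, most of which encode transcription factors, 20 fell, 2 rose and 432 did not pass, with 5 higher and 37 lower adjusted over the list alone. ZNF92 (−1.81, limma adjusted p = 0.0209), ZNF43 (−1.45, adjusted p = 0.0162), ZNF85 (−1.41, adjusted p = 0.00976) and ZNF267 (−1.34, adjusted p = 0.0158) fell, and ZNF358 (1.41) and ZNF526 (0.73), named after their values were seen, rose. The median was −0.134 (camera adjusted p = 3.51e-09, and adjusted p = 0.192 with an estimated correlation), and fry did not call the list (adjusted p = 0.0502). With quantile normalization 3 rose and 13 fell, and the median was −0.0249. Among 400 olfactory receptor genes, which serve the sense of smell, OR5J2 fell (−1.68, adjusted p = 0.0472) and 399 did not pass, with 0 adjusted over the list alone and a median of 0.117 (camera adjusted p = 0.535). OR5J2 lost its call under quantile normalization.

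Markers of cell types other than the cultured line did not pass camera's threshold in any of their lists. Among 10 astrocyte markers ALDOC, also a glycolytic enzyme, rose and 9 did not pass, with 1 higher adjusted over the list alone (median 0.0702, camera adjusted p = 0.889). Of 12 leukocyte and microglia markers CD68, a lysosomal glycoprotein, rose (1.49, limma adjusted p = 0.0132) and 11 did not pass, with 2 higher adjusted over the list alone (median 0.103, camera adjusted p = 0.324). The remaining marker lists had 0 members past limma's threshold. For 10 neuron markers 4 had an unadjusted p under 0.05, and 1 was higher and 3 lower adjusted over the list alone. Their median was 0.017 and their mean −0.192, and camera gave a downward direction (adjusted p = 0.234). Of 8 oligodendrocyte markers 1 had an unadjusted p under 0.05 (median 0.176, camera adjusted p = 0.523), as had 2 of 10 epithelial markers, 1 of them higher adjusted over the list alone (median 0.224, camera adjusted p = 0.324). For 9 endothelial and 7 fibroblast markers 0 had an unadjusted p under 0.05, with medians of 0.0554 and −0.087 (camera adjusted p = 0.939 and 0.305). The list of mitochondrially encoded transcripts had 0 members under its gene symbols.

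**Figure D3:**
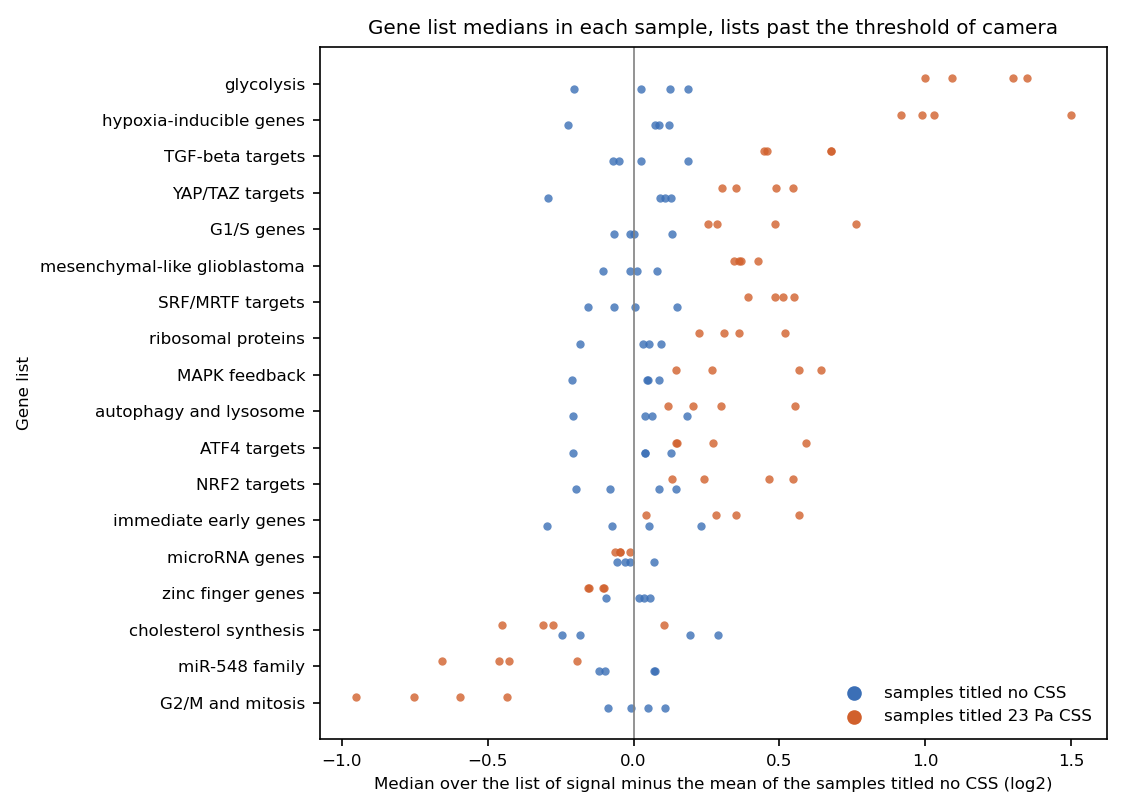
Median over each gene list of the log2 signal minus the mean of the samples titled no CSS, 1 point per sample, for the lists past camera's threshold. The glycolysis and hypoxia lists lie highest in all 4 samples titled 23 Pa CSS and the G2/M list has a median difference of −0.609, while the immediate early, ATF4, NRF2 and autophagy lists change sign on arrays centred on hybridisation controls.

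In all, 13 lists passed camera's threshold upward and 5 downward. With an estimated correlation 0 lists passed in camera, 8 had an unadjusted p under 0.05, and fry called 22. By the exact test over 35 splits of the samples, 17 lists reached the smallest possible p of 0.0286, which was 0.0824 after adjustment over the lists. Centring the arrays on their hybridisation controls moved the median difference of all transcript clusters from 0.03 to −0.28, which lowered each list median by 0.311 and turned the sign of 31 of the 49, 4 of them past camera's threshold.

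The samples separated by group along the first principal component, which held 34.7% of the variance, with 14.2% on the second. The samples titled no CSS lay between −104.8 and −56.4, and those titled 23 Pa CSS at 119.5, 94.8, 2.69 and 80.5. Titled 23 Pa CSS replicate 3 thus lay between the groups, and its mean correlation was 0.977 with its own group and 0.98 with the other, yet its hypoxia median was the highest of the 4 samples. Pairwise correlations of all samples ranged from 0.961 to 0.985.

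**Figure D4:**
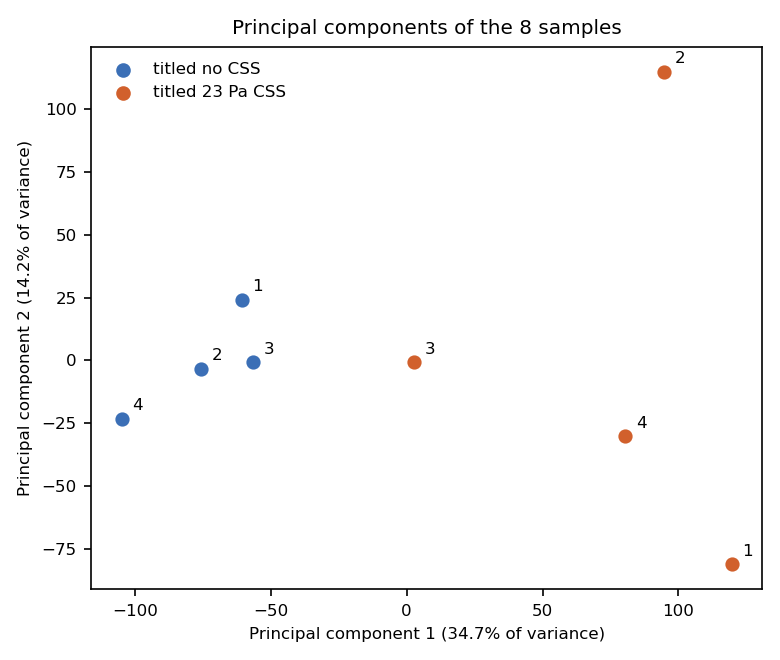
First and second principal component of the 8 samples, from the log2 signal of all 135750 transcript clusters, with the replicate number beside each point. The 4 samples titled no CSS lie between −104.8 and −56.4 on the first component, and titled 23 Pa CSS replicate 3 lies at 2.69.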

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

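The comparisons of control signal in this section were not planned before the data were examined. Within each group of 4, a sample was taken to stand apart when its gap to the nearest of the other 3 exceeded the share of the group's range that Dixon's test sets at 95%. This was the case in 24 of 420 groups of values, where chance alone gives about 21, and 10 of the 24 fell on titled no CSS replicate 4.

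In titled no CSS replicate 4 the signal of CDKN1A was 10.21, against 10.68 to 10.77 in the other 3 samples of its group. JUN was 7.68 there, against 8.55 to 8.71, and ETV5 was 12.99, against 13.65 to 13.74. SNORA13 was 9.41 in this sample, against 9.72 to 9.74, and LDHA was 19.41, against 19.69 to 19.71. The medians of 5 gene lists, relative to the mean of the samples titled no CSS, were low in it as well. They were −0.224 for the hypoxia list (0.0749 to 0.123 in the others), −0.293 for YAP/TAZ targets (0.0911 to 0.128), −0.211 for ERK feedback genes (0.0447 to 0.0856), −0.188 for mesenchymal-transition genes (0.0248 to 0.0632) and −0.169 for the unfolded protein response (0.0561 to 0.0651). Control signal was also lowest of all 8 samples here, at 9.972 for hybridisation controls (10.16 to 10.66 in the others). It was 6.925 for poly-A spikes (7.209 to 8.031) and 12.9 for positive controls in exons (13.15 to 13.47). None of these control values stood apart by Dixon's test, and the median of all transcript clusters, 4.625, was not the lowest.

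In the other samples titled no CSS, BHLHE40 was 13.60 in replicate 2, against 13.31 to 13.33. In replicate 3, MIR454 was 8.68, against 8.32 to 8.35, ERO1A was 14.63, against 14.71 in the others, and the median of the epithelial markers was −0.0978, against 0.0425 to 0.0621. Among the samples titled 23 Pa CSS, replicate 1 had 12.81 for ALDOC (12.33 to 12.39 in the others), 7.10 for CDT1 (6.37 to 6.47), 17.25 for FTL (16.75 to 16.82), 12.67 for BUB1 (13.26 to 13.32) and a median of 0.186 for interferon-stimulated genes (0.0341 to 0.0396). Replicate 2 had 4.70 for ANKRD1 (3.85 to 3.997), 19.85 for GAPDH (19.89 in the others), −0.115 for the median of matrix components (0.365 to 0.437) and 0.217 for that of the progenitor markers (0.0521 to 0.0643). Replicate 3 had 9.58 for ADM, against 9.35 to 9.38. No explanation was tested for these values.

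Control signal outside the comparison also differed between the groups (titled 23 Pa CSS minus titled no CSS, exact permutation test, n = 4 per group). The poly-A spikes, RNA added before labelling, differed by 0.548, the hybridisation controls by 0.311, the antigenomic background probes by 0.144 and the ERCC controls by 0.117. Each of these 4 had an exact p of 0.0286, the smallest the design allows, and an adjusted p of 0.0429 over the 6 classes of controls. The ERCC controls averaged 4.27 (titled no CSS) and 4.386 (titled 23 Pa CSS), close to the background probes at 4.032 and 4.176. Their difference therefore does not show a shift of spiked RNA. Negative controls in introns differed by 0.0349 (exact p = 0.686) and positive controls in exons by 0.218 (exact p = 0.0571).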

How the results depend on the processing

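Centring on hybridisation controls was chosen after the data were seen, and all other alternatives before. Of the 777 genes and 2727 transcript clusters, fewer were called with a block for the replicate number (327 genes and 1329 transcript clusters, 302 higher and 1027 lower) and with an unmoderated test (42 and 83, 60 higher and 23 lower), which has fewer degrees of freedom. Same-numbered samples did not deviate together, with correlations of −0.03, −0.018, −0.079 and −0.046, so no effect shared by a number was seen. Whether the numbers mark a shared day or culture is not stated in the labels and stays open. More were called with a filter at the median signal (1321 genes and 4370 transcript clusters, 1332 higher and 3038 lower), with an adjusted p under 0.1 (1879 and 6345, 2111 higher and 4234 lower) and at an unadjusted p under 0.05 with a 1.5-fold change (3772 and 14210, 5062 higher and 9148 lower). An unadjusted p with a 2-fold change gave 4421 transcript clusters, 3755 of them lower. Restriction to transcript clusters with a symbol gave 1659 genes, with 778 transcript clusters lower, and the trended prior gave 1183 genes, with 1197 higher. Groups from the source names swap the counts to 1938 higher and 789 lower. Leaving out 1 sample gave 124 to 1424 genes and 411 to 5360 transcript clusters, 145 to 1283 of them higher and 266 to 4077 lower. Each such fit has fewer samples, and the highest counts came without titled 23 Pa CSS replicate 3. Where no reason is given, the cause was not tested. Centring on hybridisation controls gave 1731 genes and 8581 transcript clusters, 373 higher and 8208 lower. It shifts every difference downward by the same amount, which turned the medians of the lists of immediate early genes (−0.121), matrix components (−0.0762), ATF4 targets (−0.0319), NRF2 targets (−0.0854), autophagy and lysosome genes (−0.00311) and C/D box small nucleolar RNAs (−0.147). In all it turned 31 list medians, 4 of lists past camera's threshold and 27 of others, to values between −0.294 and −0.000282, while quantile normalization turned 1 (heat shock chaperones, 0.0166) and median centring 1 (neuron markers, −0.00873). Under the other alternatives 15 to 22 lists passed, except that camera with an estimated correlation passed 0 and found 8 at an unadjusted p under 0.05. The median ranged from 0.757 to 1.36 for the hypoxia list, 0.843 to 1.21 for glycolysis, −0.92 to −0.537 for G2/M and −0.733 to −0.313 for the miR-548 family. Of 118 changed genes followed singly, not all of them named, 106 lost their call in the unmoderated test, 81 without at least 1 sample, 45 with the block, 20 after centring on controls, 8 with the mean of all transcript clusters and 7 after quantile normalization, and 0 reversed. The 20 were CCN1, CCN2, CRIM1, PTPN14, EGR3, MYC, MMP14, FSCN1, S100A11, CDT1, AEN, BAG3, SLC3A2, CCND1, SNORA20, SNORA13, SNORA71C, MIR3654, ZNF526 and COLGALT1. Array signal carries no depth, a rise near the table's maximum cannot be seen, and the size of a change is not known where a group lies below the background probes.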

Other observations

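The gene groups in this paragraph were chosen after the values of the genes had been seen, so their medians are given without a test. Of 28 measured genes for large coiled-coil proteins of the centrosome, the Golgi apparatus, endosomes and the nuclear pore, 12 fell in limma in the samples titled 23 Pa CSS, 0 rose and 16 did not pass, with differences from −1.47 to 0.52. Those that fell included TPR of the nuclear pore basket (−2.48, adjusted p = 0.0322), the anchoring protein AKAP9 (−2.32, adjusted p = 0.0223), the endosomal tether EEA1 (−2.25, adjusted p = 0.0383), the actin-binding CCDC88A (−2.31, adjusted p = 0.0159) and the centriole protein CEP152 (−1.98, adjusted p = 0.0138). The median difference of the 28 was −1.01, and it was −1.65, −0.699, −0.574 and −1.04 in the single samples titled 23 Pa CSS. Genes that modify collagen or help secreted proteins to fold rose in part, 5 of 19 measured. They were the prolyl hydroxylase subunits P4HA2 (2.05) and P4HA1 (1.57), the lysyl hydroxylase PLOD1 (1.25), the folding oxidase ERO1A (1.24) and the glycosyltransferase COLGALT1 (0.85). The median of the 19 was 0.331, and 0.0201 on arrays centred on hybridisation controls. Of 18 genes of glycogen metabolism the glycogen synthase GYS1 (2.21), the branching enzyme GBE1 (2.00) and the phosphoglucomutase PGM1 (1.17) rose, with a median of 0.236 that became −0.0754 on arrays so centred. BNIP3P4, another pseudogene of BNIP3, fell (−2.25, adjusted p = 0.0304).

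Of 19505 protein-coding transcript clusters 370 rose and 243 fell, and of 531 small nucleolar RNAs 19 rose and 2 fell. Of 3267 long non-coding RNAs 6 rose and 22 fell, and of 1506 microRNAs 2 rose and 17 fell. Among 9618 pseudogenes 66 rose and 51 fell, and among 1032 transcribed pseudogenes 6 rose and 21 fell. Of 98455 transcript clusters without a symbol 298 rose and 1570 fell. Of 22 transcript clusters of the mitochondrial chromosome 0 passed limma's threshold, 9 had an unadjusted p under 0.05, and their median difference was 0.01. Differences between the classes were not tested.

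In the patterns weighed here, the tests against a scaling offset between the arrays were chosen after the result was seen, and the other tests before. Directions follow the titles and turn under the source names. The intervals and the random lists below treat the members of a list as independent and do not measure the spread between samples. Hypoxia-inducible genes had a median difference of 1.07 (bootstrap interval of 95%, 0.609 to 1.71). A scaling offset between the arrays is argued against by the largest shift of any hybridisation control, 0.418, which lies below that interval, whereas the poly-A spikes, added before labelling, shifted by 0.359 to 0.75 and reach into it. A rise of all genes at this signal level is argued against as well, since 0% of 10000 random lists matched for signal reached the median, and 95% of them lay between −0.0875 and 0.299. The agar cushion and the weight on it cannot be told apart, because 0 samples had a cushion without a weight.

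Genes of G2 and mitosis had a median difference of −0.609, with −0.953, −0.594, −0.752 and −0.433 in the single samples titled 23 Pa CSS. Among 4150 other protein-coding genes with at least the lowest signal of the list, short genes lay higher and long genes lower, with median differences of 0.295 up to 10 kb and −0.0505 beyond 100 kb of genomic span. Removing this trend left the G2/M median at −0.859 (−1.22 to −0.521), and the 12 members of shorter span alone had −0.455 (−0.625 to −0.264), against −1.23 (−2.04 to −0.526) for the 12 longer ones. A scaling offset is argued against by the difference from the G1/S list of −1.05 (−1.64 to −0.734). A fall of mitotic transcripts as a class may account for the part that short members share, but genes outside the list such as the endosomal EEA1 fell as well, and transcript length and base composition were not tested, so the cause stays open.

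The miR-548 family had a median difference of −0.422, or −0.401 without its 1 host gene. Random lists of 3 kinds matched for signal did not reach it: 0% of lists of all genes (95% of them between 0.0127 and 0.186), 0% of lists of other microRNA genes (−0.166 to 0.0034) and 0% of lists of transcript clusters without a symbol (−0.127 to 0.0506). These lists leave out the correlation within the family, estimated at 0.107, with which camera gave an adjusted p of 0.192. They show only that other genes and transcript clusters of this signal did not fall alike. The 27 members whose host gene had a difference of at least 0 had a median of −0.495 (−0.594 to −0.187). The 16 with a host below 0 had −0.564 (−0.792 to −0.398), so the median was negative on either side of this cut. The cut depends on scaling, since hosts such as ARHGAP6 (0.00587) and MTUS1 (0.0446) would lie below 0 on arrays centred on hybridisation controls. Some hosts, such as PCDH15 (mean signal 3.47) and CAMK1D (3.68), lay below the antigenomic background, and strand was not compared. An effect of the hosts is therefore not excluded for the family. MIR548T, MIR548AJ2 and MIR548AA1, the 3 that fell and have a measured host, are among those 16, so for them it stays open as well. These microRNAs derive from a repeated element, and signal shared between repeats was not tested and stays open.

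Other splits of the 8 samples tell which counts chance could give. Of all 35 splits, 1, the real one, reached 2727 transcript clusters and 1, again the real one, reached 777 genes. The highest of the other splits was 0 for both. Every other split mixes the groups, which widens the spread within them and makes calls unlikely. The share of 0.0286 is the smallest that 35 splits allow, so chance is argued against for these counts only down to that share. For the 18 gene lists past camera's threshold chance cannot be excluded: 2 of 35 splits gave as many, and the other one, which exchanges titled no CSS replicate 3 with titled 23 Pa CSS replicate 2, gave 21.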
